A study of Mus musculus with 16 samples.

How the data were processed

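The series holds 16 samples of caecal intestinal epithelial cells of C57BL/6 mice. The 9 RNA libraries were used, 3 each of vehicle with mock gavage, ampicillin with mock gavage and ampicillin with tributyrin, and groups and replicate numbers were taken from the sample titles. The 7 chromatin immunoprecipitation and input samples were not analysed here. Per the labels' protocols, cells were released from the tissue with DTT and EDTA and then Dispase, RNA was purified on RNeasy columns and libraries were made with the NEBNext Ultra II kit. No sort that would remove blood cells or lymphocytes is described in the labels.

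The deposited table gives TPM values per gene and library, made by the authors, with gene IDs and symbols for 24091 genes. Per the submitters' processing notes, Salmon 0.8.2, DESeq2 1.20.0 and the build mm10 were used, with no role or order stated, and the index, the annotation, the step from transcripts to genes, any filter and the strand setting are not given in the sources used here. Each library's TPM values sum to between 999833 and 999866, and TPM divides by transcript length and total, so the values keep no depth, no interval for counting error could be given, and a count model was not used. The measured precision is the spread between the 3 libraries of a group. As TPM is relative, a rise in some transcripts lowers the others. Values of short transcripts are unstable: 1190 entries of the table are microRNA, small nucleolar and other short RNA, of which 430 passed the filter. Near-identical genes, such as Hspa1a and Hspa1b, the haemoglobin genes, the defensins, the Cyp2d cluster, Mt1 and Mt2, Reg3b and Reg3g and the Gsta and Gstm genes, share reads, and the division between them is uncertain. With no strand setting known, overlapping genes on opposite strands cannot be told apart either.

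Gene IDs were matched to a RefSeq table of assembly GRCm38.p6, the same build as mm10, and 24045 of 24091 matched, with 12145 of the 12155 tested. Positions printed are those of whole genes in that table. A spreadsheet had turned 26 symbols into dates, and these were not named. All 9 columns of values matched a sample.

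Genes were kept where the mean TPM over the 9 libraries was at least 1, which kept 12155 and left out 11936, of which 4439 were at 0 in each library. Values were taken as log2(TPM + 1). A linear model with 1 mean per group was fitted to all 9 libraries in limma 3.58.1 under R 4.3.3, with 6 residual degrees of freedom and moderated variances with a trend on mean expression, and without the replicate number as a block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. An exact permutation test of 3 libraries against 3 cannot give a two-sided p below 0.1 for a single gene. Ampicillin was compared with vehicle, tributyrin with mock gavage among ampicillin libraries, and ampicillin with tributyrin against vehicle. The overlap of comparisons that share libraries was set beside the overlap of independent lists and beside 100 simulated data sets with no effect. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

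Gene lists, the design and the alternatives were fixed before the data were examined. The 39 lists were: antimicrobial and microbiota-responsive epithelial genes, MHC class II presentation, interferon-stimulated genes, mitochondrial beta-oxidation, butyrate uptake, activation, sensing and ketone metabolism, PPAR-alpha targets, dietary lipid absorption and chylomicron assembly, cholesterol biosynthesis, fatty acid synthesis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, glycolysis and hypoxia, cell cycle, ion, bicarbonate and water transport, xenobiotic metabolism, bile acid handling, circadian clock, unfolded protein and amino acid stress response, immediate early and dissociation stress genes, lysine acyltransferases, deacylases and acyl readers, genes commonly raised by deacetylase inhibition, cell junctions and barrier, sex-linked genes, and markers of stem, goblet, Paneth and deep crypt secretory, enteroendocrine, tuft, absorptive colonocyte, small intestinal enterocyte, T and intraepithelial lymphocyte, B and plasma, myeloid, fibroblast, smooth muscle, endothelial, erythroid, mast and pancreatic acinar cells. The 30 lists with at least 4 tested genes, sex-linked genes aside, were tested with camera at a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry. Camera asks whether a list moved relative to the other genes, and fry whether its genes moved on balance one way.

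Genes named in the text are, for each comparison, the 12 highest and 12 lowest log2 fold changes among called genes whose libraries do not overlap between the groups, leaving out predicted and unnamed genes and pseudogenes, and up to 4 called members of each list by size of change. Ep300, Hdac1 to Hdac3, Slc16a1 and Slc5a8 could be named in any comparison. Some genes that the rule takes are not reported here.

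The alternatives were pseudocounts of 0.1 and 5, no filter, a minimum mean TPM of 5, median-of-ratios scaling, quantile normalization, the top 50 genes left out, only the 2 groups compared in the fit, a replicate block, array weights, robust moderation, a minimum log2 change of 1, an estimated list correlation and leaving out each library in turn. Leaving out short RNA entries was added after seeing the data. The procedure was tested on simulated data in which a set of genes was changed by known amounts, and recovery is given over those of them that passed the filter and lay outside the cholesterol list, which was raised as well. For ampicillin against vehicle (12063 genes) it recovered 59.7%, 84.8% and 98.4% of genes changed by 0.5, 1 and 2 on the log2 scale, and 3.93% of its calls were false. For tributyrin against mock (12057 genes) these were 74.6%, 93.8% and 97.0%, with 8.84% false, and for ampicillin with tributyrin against vehicle (12072 genes) 62.1%, 92.2% and 95.1%, with 4.47% false.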

Results

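RNA was measured in epithelial cells isolated from the caecum of C57BL/6 mice, a common inbred laboratory strain. The caecum is the pouch at the start of the large intestine in which gut bacteria ferment fibre to butyrate and other short-chain fatty acids. The 9 RNA libraries fell into 3 groups of 3. All mice drank water with Splenda, a sweetener given as the vehicle, at 10 g/L, and in 2 of the groups the water also held ampicillin, an antibiotic, at 1 g/L. On day 7 the vehicle group and 1 ampicillin group received a mock gavage of 25% glycerol. The other ampicillin group received tributyrin, the ester of glycerol with butyrate, which lipases split into free butyrate, and cells were collected 6 h after the gavage. The series concerns butyrylation of histones in the mouse intestine and the part of the microbiota in it. Its other 7 samples, 2 immunoprecipitations of H3K27 butyrylation, 2 of H3K27 acetylation, 1 of H3K4 trimethylation, 1 of H3K27 trimethylation and 1 input, were not analysed here.

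Expression was given as TPM, a transcript abundance scaled to a fixed total, for 24091 genes, and TPM keeps no record of sequencing depth, so the depth of each library is unknown. Between 17242 and 17722 genes had a TPM above 0 in a library, and between 11746 and 12239 had a TPM of at least 1. Across the 12155 genes kept for testing, log2 values correlated at 0.976 to 0.981 in the 9 pairs of libraries within a group and at 0.964 to 0.975 in the 27 pairs between groups, with genes not being independent replicates. The first principal component held 26.2% of the variance and separated the vehicle libraries from both ampicillin groups. The second held 19.0% and separated mock from tributyrin among the ampicillin libraries. One short transcript entry, Mir6236, took 2.14%, 4.48% and 2.57% of all TPM in vehicle replicates 1 to 3. It took 4.04%, 1.24% and 1.24% in the ampicillin replicates with mock gavage and 0.857%, 0.705% and 0.863% in the tributyrin replicates. As TPM is relative, this difference between the groups shifts the values of other genes slightly. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. Unless stated otherwise, TPM values are mean ± SD with n = 3 libraries, and log2 fold changes are on the scale of log2(TPM + 1), which understates the change of low genes, and are given ± SE. Each adjusted p of a gene is from limma with Benjamini-Hochberg adjustment, and each adjusted p of a gene list is from limma's camera. At its preset correlation camera also called up to 12 lists when libraries of 2 groups were mixed, so these list values may be too small. Gene positions are those of the whole gene in mouse build mm10, and values are per gene, so no exon is assigned.

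The first comparison asked what 7 days of ampicillin changed in caecal epithelial cells. Of 14 measured genes by which cells take up, sense and use butyrate and ketone bodies, 9 fell. The monocarboxylate transporter Slc16a1 (gene ID 20501, chromosome 3, 104638664 to 104658462) went from 298 ± 8.73 TPM with vehicle to 184 ± 7.50 TPM with ampicillin. Acsm3, a mitochondrial acyl-CoA synthetase, went from 19.4 ± 2.81 to 10.6 ± 1.13 TPM. The sodium-coupled butyrate transporter Slc5a8 (gene ID 216225, chromosome 10, 88885992 to 88929515) went from 52.0 ± 3.62 to 26.6 ± 1.51 TPM. Of 23 genes of glycolysis and the hypoxia response 20 rose, among them the phosphofructokinase gene Pfkp (gene ID 56421, chromosome 13, 6579874 to 6649060), from 29.7 ± 7.83 to 86.2 ± 4.62 TPM.

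Among 14 measured genes of butyrate uptake, activation, sensing and ketone metabolism, 9 fell and 1 rose (median log2 fold change -0.35; adjusted p = 0.000410, and adjusted p = 0.0864 with an estimated correlation). Adjusted over the list alone, 9 fell and 2 rose. The log2 fold change was -0.94 ± 0.09 for Slc5a8 (adjusted p = 0.000226), -0.80 ± 0.12 for Acsm3 (adjusted p = 0.00220) and -0.69 ± 0.068 for Slc16a1 (adjusted p = 0.000281). The member that rose was Slc16a3, a transporter known for lactate export, from 1.24 ± 0.582 to 6.17 ± 0.828 TPM. Of 23 genes of glycolysis and the hypoxia response, 20 rose and 1 fell (median 0.56; adjusted p = 6.55e-12, and adjusted p = 0.0864 with an estimated correlation). The counts were the same adjusted over the list alone. The hexokinase gene Hk2 rose by 1.14 ± 0.11. Egln3, an oxygen sensor that is itself induced by hypoxia, went from 7.15 ± 0.768 to 18.6 ± 2.05 TPM. Nuclear-encoded genes of oxidative phosphorylation were also higher, by a smaller median of 0.13. Of 45, 11 rose and 0 fell, the same adjusted over the list alone (adjusted p = 5.33e-05, and adjusted p = 0.654 with an estimated correlation). The complex I subunit Ndufa1 stood at 434 ± 13.3 and 568 ± 42.6 TPM, and the cytochrome oxidase subunit Cox7a2 at 558 ± 29.9 and 696 ± 7.04 TPM.

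Interferon-stimulated genes were lower after ampicillin, with 18 of 28 falling and 1 rising (median -0.68; adjusted p = 5.64e-10, and adjusted p = 0.563 with an estimated correlation). Adjusted over the list alone, 20 fell and 2 rose. The antiviral enzyme gene Oas3 (gene ID 246727, chromosome 5, 120753098 to 120777684) stood at 7.24 ± 0.877 TPM with vehicle and 0.758 ± 0.269 TPM with ampicillin, a log2 fold change of -2.23 ± 0.17 (adjusted p = 6.31e-05). Psmb8 (gene ID 16913, chromosome 17, 34198195 to 34201454), a catalytic subunit of the immunoproteasome, went from 21.4 ± 2.57 to 7.18 ± 0.740 TPM. Genes of cholesterol biosynthesis were higher as a list, with 9 of 25 rising and 1 falling (median 0.21; adjusted p = 0.00121, and adjusted p = 0.729 with an estimated correlation). Adjusted over the list alone, 14 rose and 1 fell. Insig1 (gene ID 231070, chromosome 5, 28071412 to 28078662), a sterol sensor and target of SREBP2, rose from 59.4 ± 12.7 to 107 ± 5.87 TPM, and the squalene epoxidase gene Sqle changed by 0.50 ± 0.093. Immediate early and dissociation stress genes rose in 11 of 20 cases and fell in 0 (median 0.40; adjusted p = 5.33e-05, and adjusted p = 0.563 with an estimated correlation), or in 13 adjusted over the list alone. Among them Atf3, a stress-induced transcription factor, went from 103 ± 26.6 to 215 ± 18.1 TPM and the phosphatase gene Dusp1 from 101 ± 11.3 to 191 ± 9.58 TPM.

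Of 9 measured markers of Paneth and deep crypt secretory cells, 7 fell and 0 rose (median -1.90; adjusted p = 5.33e-05, and adjusted p = 0.563 with an estimated correlation), or 9 adjusted over the list alone. Mptx1, a pentraxin of crypt secretory cells, went from 24.8 ± 4.60 to 6.07 ± 2.23 TPM. Defensins and other small intestinal genes of this kind were not even among the vehicle libraries. Defa24 was at 30.9 TPM in vehicle replicate 2, 0.212 in replicate 1 and 8.86 in replicate 3, and was listed at 0 in the ampicillin libraries. The same vehicle replicate had the highest value of all 17 small intestinal, Paneth cell and lipid transport genes that reached 1 TPM in a vehicle library and averaged under 1 TPM with ampicillin and mock. Of 15 goblet cell markers, 5 fell and 0 rose, the same adjusted over the list alone (median -0.30; adjusted p = 0.0254, and adjusted p = 0.729 with an estimated correlation). This list lost its call without vehicle replicate 1 (adjusted p = 0.285) or ampicillin replicate 3 (0.0590), and with array weights (0.121). The goblet cell genes Klk1, from 647 ± 5.17 to 405 ± 36.3 TPM, and Spink4, from 5373 ± 409.9 to 3455 ± 414 TPM, were among those that fell. Of 15 stem cell markers, 4 fell and 0 rose, the same adjusted over the list alone (median -0.14; adjusted p = 0.0144, and adjusted p = 0.729 with an estimated correlation). Lgr5, which marks crypt base stem cells, went from 9.98 ± 0.938 to 5.98 ± 0.517 TPM.

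**Figure D1:**
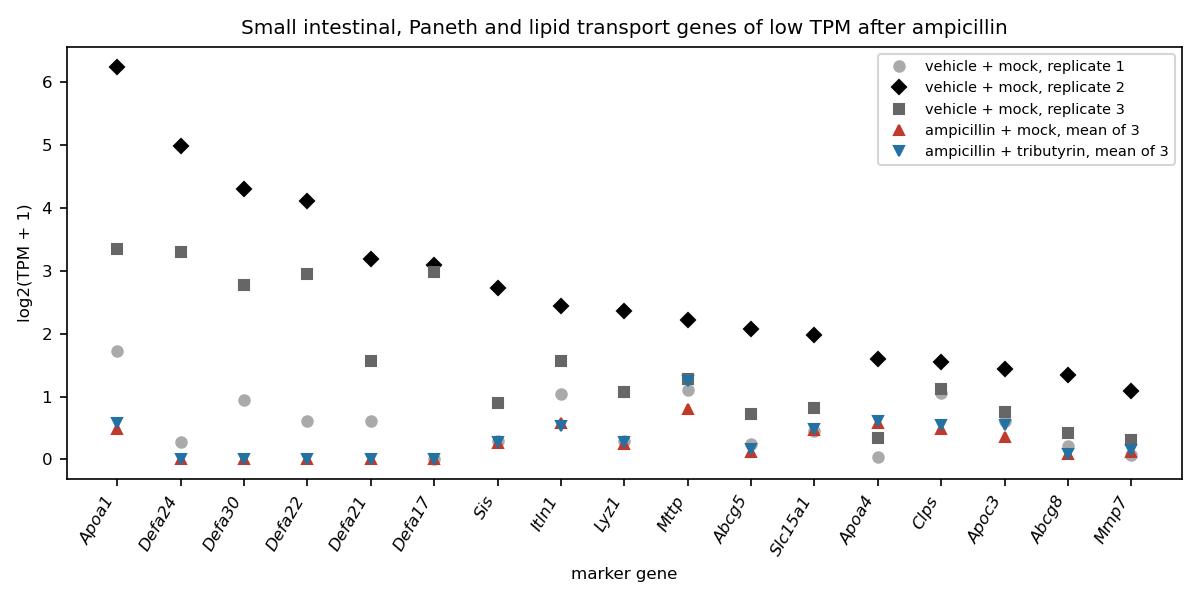
Expression of 17 small intestinal, Paneth cell and lipid transport genes, as log2(TPM + 1), in each of the 3 vehicle libraries and as the mean of the 3 libraries of each ampicillin group. Vehicle replicate 2 (black diamonds) has the highest value for all 17 genes.

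Of 17 absorptive colonocyte markers, 8 fell and 3 rose, or 9 and 3 adjusted over the list alone (median -0.41; adjusted p = 0.0244, and adjusted p = 0.654 with an estimated correlation). The differentiation keratin Krt20 went from 1082 ± 179 to 567 ± 22.2 TPM, and the sodium-proton exchanger Slc9a3 moved the other way, from 32.7 ± 8.61 to 89.7 ± 19.2 TPM. Of 19 genes of mitochondrial beta-oxidation, 6 fell and 2 rose, the same adjusted over the list alone (median -0.10; adjusted p = 0.0352, and adjusted p = 0.654 with an estimated correlation). The call of this list was lost without vehicle replicate 3 (adjusted p = 0.0628), ampicillin replicate 3 (0.0568) or tributyrin replicate 1 (0.0519), and with quantile normalization (0.0607). Decr1, which handles unsaturated fatty acids, had a log2 fold change of -0.54 ± 0.059 and the electron carrier subunit Etfb one of -0.43 ± 0.071. Of 33 cell cycle genes, 1 fell, the same adjusted over the list alone, and the list as a whole lay lower (median -0.08; adjusted p = 0.0254, and adjusted p = 0.755 with an estimated correlation). That call was lost without vehicle replicate 1 (adjusted p = 0.0757), vehicle replicate 2 (0.309) or ampicillin replicate 2 (0.386). The 1 gene was Mcm6, a subunit of the replicative helicase, at a log2 fold change of -0.32 ± 0.068.

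The largest single changes included Cyp2d34 (gene ID 223706, chromosome 15, 82615963 to 82620956), a cytochrome P450 gene, at 6.96 ± 0.758 TPM with vehicle and 102 ± 10.0 TPM with ampicillin (log2 fold change 3.70 ± 0.10, adjusted p = 8.94e-07). It belongs to a cluster of near-identical genes, so its share of the cluster's reads is uncertain. Saa3 (gene ID 20210, chromosome 7, 46711998 to 46719615), an acute phase gene, went from 28.5 ± 2.76 to 244 ± 46.5 TPM, and Ak4, a mitochondrial adenylate kinase, from 2.92 ± 0.964 to 31.2 ± 2.40 TPM. The metallothionein genes Mt1 (gene ID 17748, chromosome 8, 94178883 to 94180327) and Mt2, which bind zinc and are close relatives, went from 675 ± 79.4 to 2416 ± 109.8 TPM and from 354 ± 38.1 to 1412 ± 97.4 TPM. The transferrin receptor gene Tfrc went from 86.6 ± 11.7 to 303 ± 18.8 TPM. The calcium channel Trpv6 (gene ID 64177, chromosome 6, 41620619 to 41636405) fell from 14.8 ± 3.78 to 0.327 ± 0.116 TPM (log2 fold change -3.55 ± 0.16, adjusted p = 7.44e-06). The chemokine Ccl6 fell by a log2 fold change of -3.78 ± 0.22. Fut2 (gene ID 14344, chromosome 7, 45648591 to 45666394), the fucosyltransferase by which the epithelium decorates its surface for bacteria, fell from 34.5 ± 2.55 to 7.44 ± 0.970 TPM. Tropomyosin 2, Tpm2, fell from 25.5 ± 0.459 to 1.94 ± 0.403 TPM.

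Of 12155 genes tested, 2587 changed at an adjusted p under 0.05, 1343 higher and 1244 lower with ampicillin, and 267 of them changed by at least 1 on the log2 scale. The median size of a called change was 0.40, and the libraries of the groups did not overlap for 40.8% of genes tested, against 10% by chance for 3 against 3. Of 30 lists tested, camera called 12, and with an estimated correlation it called 0, with an unadjusted p under 0.05 for 2. Limma's fry, which does not compare a list with other genes, called 9, and 8 lists were called by both. By fry the cholesterol (adjusted p = 0.0642), stem cell (0.0801), goblet cell (0.112) and cell cycle lists (0.420) were not called. Fry alone called the genes commonly raised by deacetylase inhibition (0.000341). Of these 10 genes 4 rose and 3 fell, with a median of -0.025, so they did not move 1 way as a set.

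**Figure D2:**
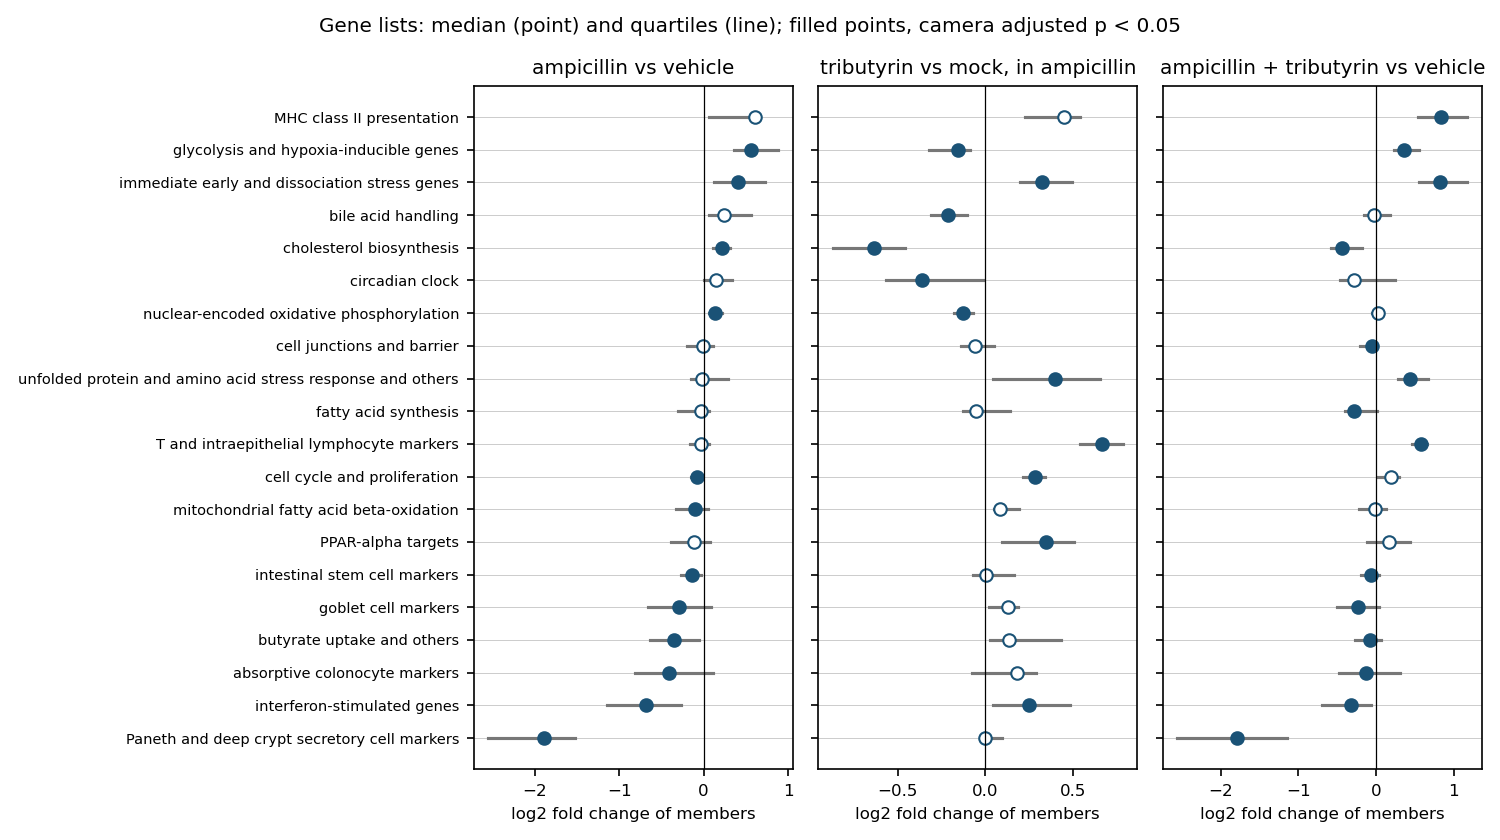
Median (points) and quartiles (lines) of the log2 fold changes of the members of the 20 gene lists called in at least 1 comparison, 1 panel per comparison with its own x scale. Filled points passed camera's adjusted p of 0.05, such as glycolysis and hypoxia with a median of 0.56 after ampicillin and cholesterol biosynthesis with -0.63 after tributyrin.

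The second comparison asked what tributyrin changed within 6 h in ampicillin-treated mice. Of 25 genes of cholesterol biosynthesis 21 fell: the sterol sensor Insig1 went from 107 ± 5.87 to 43.2 ± 3.67 TPM, and squalene synthase, Fdft1 (gene ID 14137, chromosome 14, 63145150 to 63181687), from 50.2 ± 4.16 to 26.0 ± 0.906 TPM. Hspa5 (gene ID 14828, chromosome 2, 34772090 to 34776529), the main chaperone of the endoplasmic reticulum, rose from 250.4 ± 8.93 to 505 ± 29.3 TPM. The transporter gene Slc16a1 rose from 184 ± 7.50 to 281 ± 26.0 TPM. Angptl4 (gene ID 57875, chromosome 17, 33774900 to 33781575), a PPAR target that inhibits lipoprotein lipase, rose from 1.01 ± 0.170 to 5.92 ± 1.27 TPM.

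Of 25 genes of cholesterol biosynthesis, 21 fell and 0 rose, or 22 adjusted over the list alone (median -0.63; adjusted p = 1.38e-17, and adjusted p = 0.311 with an estimated correlation). The log2 fold change was -1.28 ± 0.13 for Insig1 (adjusted p = 0.000702) and -0.92 ± 0.08 for Fdft1 (adjusted p = 0.000425). Of 22 genes of the unfolded protein and amino acid stress response, 12 rose and 1 fell, the same adjusted over the list alone (median 0.40; adjusted p = 0.000128, and adjusted p = 0.411 with an estimated correlation). Beside Hspa5, at 1.01 ± 0.075 (adjusted p = 0.000367), the serine synthesis enzyme Phgdh rose by 0.97 ± 0.07 (adjusted p = 0.000317), and Creld2, a secreted protein of endoplasmic reticulum stress, went from 38.2 ± 1.12 to 71.2 ± 4.62 TPM. Immediate early and dissociation stress genes rose in 11 of 20 cases, or 13 adjusted over the list alone, and fell in 0 (median 0.32; adjusted p = 4.90e-05, and adjusted p = 0.411 with an estimated correlation). The members with the highest log2 fold changes were heat shock genes. Hspa1b (gene ID 15511, chromosome 17, 34956429 to 34959238), which shares reads with its near-identical neighbour Hspa1a, went from 23.6 ± 4.73 to 88.0 ± 18.2 TPM and Hsph1 from 21.2 ± 1.54 to 51.6 ± 5.14 TPM.

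Of 14 genes of butyrate uptake, activation, sensing and ketone metabolism, 5 rose and 1 fell, or 7 and 1 adjusted over the list alone. The list as a whole was not called by camera (adjusted p = 0.106), which compares it with the other genes. Fry, which makes no such comparison, did call it (adjusted p = 0.000730 by fry). Slc16a1 rose by 0.60 ± 0.068 (adjusted p = 0.00100), while Slc5a8 stood at 26.6 ± 1.51 and 24.4 ± 2.96 TPM (adjusted p = 0.339). PPAR-alpha targets rose in 11 of 19 cases, or 12 adjusted over the list alone, and fell in 0 (median 0.35; adjusted p = 0.000814, and adjusted p = 0.489 with an estimated correlation). Angptl4 changed by 1.77 ± 0.19 (adjusted p = 0.000805), and Acot1, an acyl-CoA thioesterase, by 0.83 ± 0.091. Glycolysis and hypoxia genes fell in 9 of 23 cases, or 10 adjusted over the list alone, and rose in 0 (median -0.15; adjusted p = 2.11e-06, and adjusted p = 0.311 with an estimated correlation). Hk2 changed by -0.58 ± 0.11, and Egln3 stood at 18.6 ± 2.05 and 10.9 ± 0.351 TPM. Oxidative phosphorylation genes fell in 7 of 45 cases, or 3 adjusted over the list alone, and rose in 0 (median -0.13; adjusted p = 1.61e-08, and adjusted p = 0.411 with an estimated correlation). Cox7a2 went from 696 ± 7.04 to 597 ± 8.76 TPM. Of 6 bile acid genes 3 fell, or 4 adjusted over the list alone (median -0.21; adjusted p = 0.0154, adjusted p = 0.411 with an estimated correlation). Quantile normalization ended that call (adjusted p = 0.0672). Of 16 circadian clock genes, 5 fell and 3 rose, or 9 and 3 adjusted over the list alone (median -0.36; adjusted p = 0.00551, and adjusted p = 0.411 with an estimated correlation). Among them the repressor gene Per1 went from 11.6 ± 0.939 to 6.99 ± 0.809 TPM, and Nfil3 rose by 0.56 ± 0.09.

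Cell cycle genes rose in 7 of 33 cases, or 13 adjusted over the list alone, and fell in 0 (median 0.29; adjusted p = 0.000998, and adjusted p = 0.778 with an estimated correlation). Birc5, a regulator of chromosome segregation and survival, went from 62.9 ± 7.67 to 86.7 ± 5.16 TPM, and the helicase subunit Mcm3 from 29.2 ± 2.18 to 40.5 ± 3.97 TPM. Interferon-stimulated genes rose in 10 of 28 cases, or 11 adjusted over the list alone, and fell in 0 (median 0.25; adjusted p = 0.0137, and adjusted p = 0.778 with an estimated correlation). This call was lost without ampicillin replicate 3 (adjusted p = 0.140) or tributyrin replicate 1 (0.183). The immunoproteasome genes Psmb8, from 7.18 ± 0.740 to 16.2 ± 0.374 TPM, and Psmb9, from 13.7 ± 1.53 to 25.1 ± 2.04 TPM, rose, while Oas3 stood at 0.758 ± 0.269 and 0.907 ± 0.365 TPM. Markers of T cells and intraepithelial lymphocytes were also higher, with 6 of 14 rising, or 13 adjusted over the list alone, and 0 falling (median 0.67; adjusted p = 0.000814, and adjusted p = 0.775 with an estimated correlation). Among the tributyrin libraries all 14 were highest in replicate 2, and the list kept its camera call without that library. Their estimated correlation was 0.733, so the 14 genes are not independent evidence. The granzyme gene Gzma (gene ID 14938, chromosome 13, 113093824 to 113100981) went from 0.468 ± 0.274 to 3.82 ± 0.980 TPM, and the chemokine Ccl5 rose by 1.23 ± 0.24. The haemoglobin gene Hba-a2 (gene ID 110257, chromosome 11, 32296492 to 32297310), a product of red cells with near-identical copies, rose by 2.44 ± 0.44 on the log2 scale (adjusted p = 0.00598) and Hbb-bs from 8.62 ± 4.39 to 42.6 ± 7.43 TPM.

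Of 34 measured lysine acyltransferases, deacylases and acyl readers, 4 rose and 1 fell, and the list was not called (adjusted p = 0.930). The class I deacetylase gene Hdac1 (gene ID 433759, chromosome 4, 129516104 to 129542646) rose from 187 ± 6.09 to 272 ± 16.5 TPM (log2 fold change 0.54 ± 0.053, adjusted p = 0.000573) and Hdac3 from 65.5 ± 0.656 to 85.8 ± 3.23 TPM. Ep300, which encodes the acyltransferase p300, stood at 9.47 ± 0.301 and 9.84 ± 2.03 TPM, a change of 0.032 (adjusted p = 0.890) whose sign turned under both other scalings and without tributyrin replicate 1 or 2. Of 10 genes commonly raised by deacetylase inhibition, 3 rose and 3 fell (adjusted p = 0.418): the linker histone gene H1f0 rose from 189 ± 14.9 to 314 ± 39.1 TPM, and Mt1 fell from 2416 ± 109.8 to 1640.1 ± 88.5 TPM. Among the largest changes outside the lists, creatine kinase B, Ckb, rose from 23.0 ± 7.15 to 82.1 ± 12.7 TPM, and Cdkn2b, an inhibitor of the cell cycle kinases CDK4 and CDK6, fell from 65.1 ± 2.95 to 32.8 ± 5.16 TPM.

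Tributyrin changed 2819 of 12155 genes, 1902 higher and 917 lower, with 116 changed by at least 1 on the log2 scale and a median called change of 0.36. The share of higher calls, 67.5%, depended on the scaling. With median-of-ratios scaling 1514 genes were higher and 1512 lower, and with quantile normalization 1466 were higher and 1647 lower, a share of 47.1%. With short RNA entries left out, an alternative added after seeing the data, the share was 62.2%. The count was 1749 without ampicillin replicate 1, 1659 without ampicillin replicate 2 and 1574 without tributyrin replicate 2. The groups' libraries did not overlap for 42.6% of genes, against 10% by chance. Camera called 11 of 30 lists, and with an estimated correlation 0, with an unadjusted p under 0.05 for 2. Fry called 11 as well, and 9 lists were called by both. By fry the cell cycle and bile acid lists were not called (adjusted p = 0.103 for each). Fry alone called the butyrate and ketone (0.000730) and beta-oxidation lists (0.0171).

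**Figure D3:**
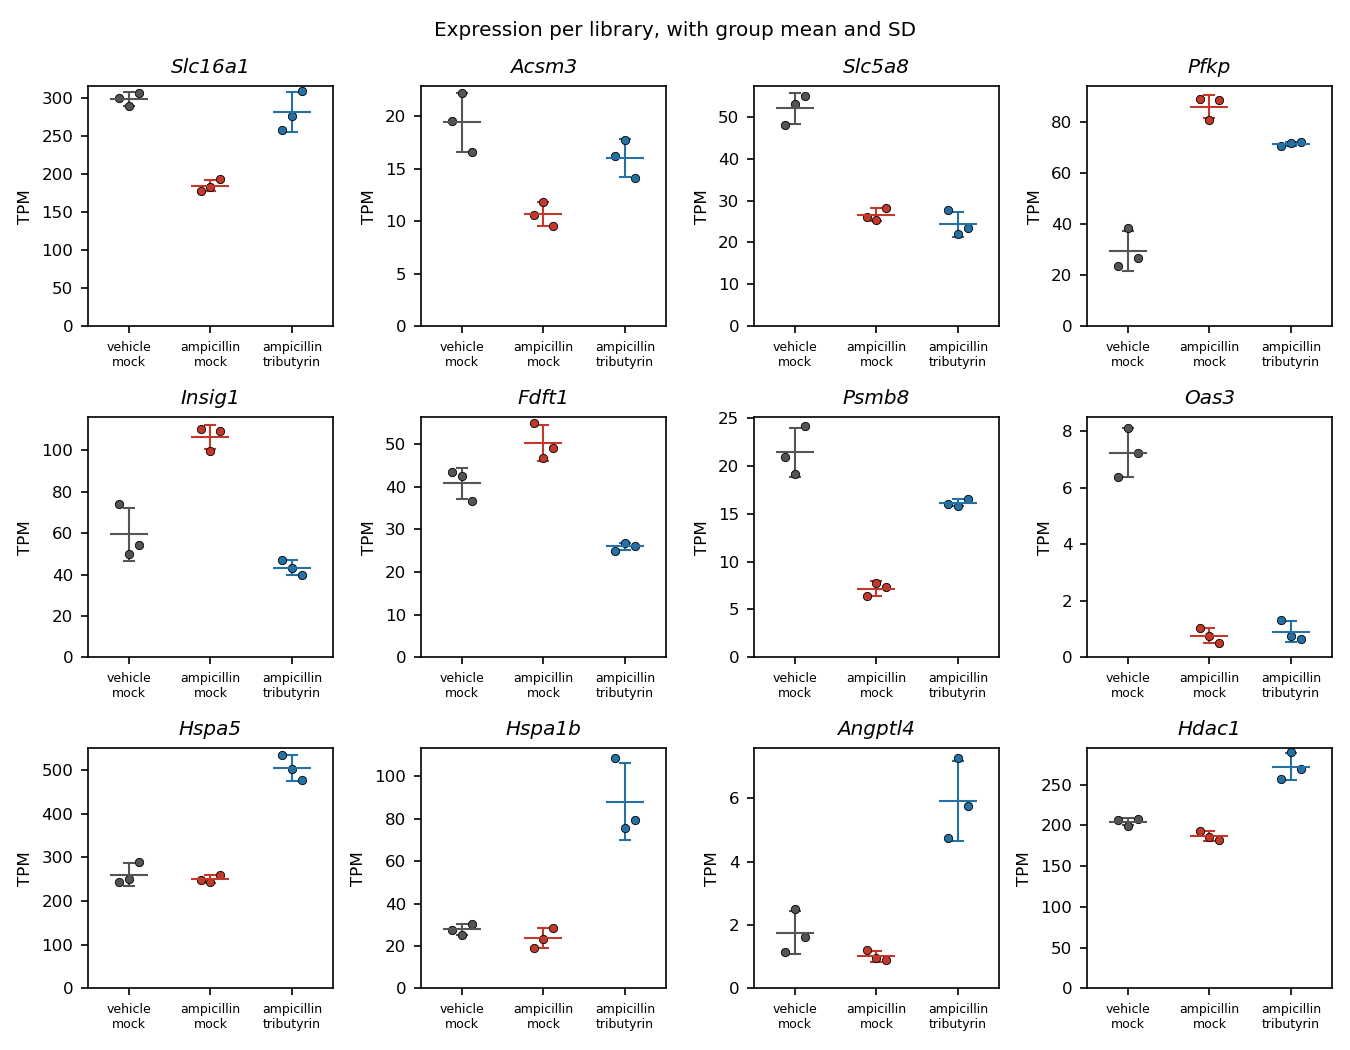
TPM of 12 genes in each of the 9 libraries (points), with group mean and SD (bars), for vehicle, ampicillin with mock gavage and ampicillin with tributyrin, each axis starting at 0. Slc16a1 and Acsm3 have their lowest means with ampicillin and mock, Slc5a8 and Oas3 stay low with tributyrin, and Hspa5 and Hspa1b are highest with tributyrin.

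The third comparison set ampicillin with tributyrin against vehicle with mock gavage, which shows what differed from vehicle after both treatments. Slc16a1 stood at 281 ± 26.0 TPM against 298 ± 8.73 TPM (adjusted p = 0.353). Slc5a8 was lower by a log2 fold change of -1.07 ± 0.09 (adjusted p = 0.000198) and Oas3 by one of -2.12 ± 0.17 (adjusted p = 0.000142). Hspa5 was higher than with vehicle by 0.95 ± 0.075 (adjusted p = 0.000145) and Hdac1, at 272 ± 16.5 TPM, by 0.41 ± 0.053.

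Immediate early and dissociation stress genes were higher in 19 of 20 cases, the same adjusted over the list alone (median 0.82; adjusted p = 6.62e-11, and adjusted p = 0.303 with an estimated correlation). The transcription factor Klf2 was higher by 1.37 ± 0.076, and Atf3 stood at 260.4 ± 10.9 against 103 ± 26.6 TPM. Genes of the unfolded protein and amino acid stress response were higher in 16 of 22 cases, or 17 adjusted over the list alone, and lower in 0 (median 0.44; adjusted p = 4.09e-07, and adjusted p = 0.303 with an estimated correlation). Glycolysis and hypoxia genes were higher in 17 of 23 cases and lower in 1, the same adjusted over the list alone (median 0.37; adjusted p = 0.000109, and adjusted p = 0.303 with an estimated correlation). Pfkp stood at 71.6 ± 0.840 against 29.7 ± 7.83 TPM. Cholesterol genes were lower in 17 of 25 cases and higher in 1, or 18 and 1 adjusted over the list alone (median -0.43; adjusted p = 1.11e-10, and adjusted p = 0.303 with an estimated correlation). Fdft1 stood at 26.0 ± 0.906 against 40.8 ± 3.64 TPM. Genes of fatty acid synthesis were lower in 7 of 13 cases and higher in 2, the same adjusted over the list alone (median -0.29; adjusted p = 0.00418, and adjusted p = 0.555 with an estimated correlation). The malic enzyme gene Me1 changed by -0.88 ± 0.084 and the elongase gene Elovl5 by 0.80 ± 0.10. Interferon-stimulated genes were lower in 12 of 28 cases and higher in 3, or 14 and 3 adjusted over the list alone (median -0.32; adjusted p = 7.45e-06, and adjusted p = 0.587 with an estimated correlation). Paneth and deep crypt secretory markers were lower in 6 of 9 cases, or 8 adjusted over the list alone, and higher in 0 (median -1.79; adjusted p = 1.07e-05, and adjusted p = 0.308 with an estimated correlation). Vehicle replicate 2, with its high small intestinal values, enters this comparison too. So does tributyrin replicate 2, the highest of its group for all 14 T cell markers. T cell markers were higher in 6 of 14 cases, or 8 adjusted over the list alone, and lower in 0 (median 0.58; adjusted p = 0.00551, adjusted p = 0.634 with an estimated correlation, and 0.110 with a minimum mean TPM of 5).

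A further 6 lists passed, and each lost its call without at least 1 library. Goblet cell markers were lower in 6 of 15 cases, or 7 adjusted over the list alone (adjusted p = 0.00551, adjusted p = 0.634 with an estimated correlation, and 0.114 without vehicle replicate 1). MHC class II genes were higher in 3 of 5, or 4 adjusted over the list alone (adjusted p = 0.0326, adjusted p = 0.587 with an estimated correlation, 0.0704 without vehicle replicate 2 and 0.0878 without tributyrin replicate 3). The highest change among them was that of the invariant chain Cd74, 1.34 ± 0.26. The butyrate and ketone list was lower in 4 of 14 and higher in 1, the same adjusted over the list alone (adjusted p = 0.0384, adjusted p = 0.303 with an estimated correlation, 0.0704 without vehicle replicate 2 and 0.0962 without tributyrin replicate 1). Stem cell markers were lower in 2 of 15, Lgr5 at -0.72 ± 0.12 being one (adjusted p = 0.0384, adjusted p = 0.634 with an estimated correlation, 0.0962 without vehicle replicate 1 and 0.138 without tributyrin replicate 3). Absorptive colonocyte markers were lower in 5 of 17 and higher in 4, or 6 and 4 adjusted over the list alone (adjusted p = 0.0384, adjusted p = 0.634 with an estimated correlation, 0.141 without vehicle replicate 2 and 0.0960 without tributyrin replicate 1). Cell junction genes were lower in 5 of 19 and higher in 3 (adjusted p = 0.0384, adjusted p = 0.634 with an estimated correlation, 0.249 without vehicle replicate 2 and 0.0946 without tributyrin replicate 1). The tight junction gene Cldn7 changed by -0.35 ± 0.051 and Cldn8 by 1.31 ± 0.11. Other settings ended some of these calls too. The MHC class II call was lost with no filter (adjusted p = 0.0531), with the top 50 genes left out (0.0971) and with array weights (0.102). The stem cell call was lost with array weights (0.101), and the butyrate and ketone call with no filter (0.108) and with quantile normalization (0.156). The absorptive colonocyte call was lost with no filter (0.0588), a minimum mean TPM of 5 (0.0989), median-of-ratios scaling (0.118), quantile normalization (0.420), the top 50 genes left out (0.176), only the compared groups in the fit (0.0534) and short RNA entries left out (0.0756), the last an alternative added after seeing the data. The junction call was lost with no filter (0.0536), a minimum mean TPM of 5 (0.0843), both other scalings (0.0527 and 0.156), array weights (0.0908) and short RNA entries left out (0.0506).

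Of 12155 genes, 3444 differed, 2325 higher and 1119 lower than with vehicle, 199 of them by at least 1 on the log2 scale, and 2061 differed without tributyrin replicate 2. The share of higher calls was 67.5%, against 47.1% with median-of-ratios scaling (1564 higher, 1757 lower) and 50.3% with quantile normalization (1683 higher, 1663 lower). The groups' libraries did not overlap for 41.7% of genes, against 10% by chance. Camera called 14 of 30 lists, and with an estimated correlation 0, with an unadjusted p under 0.05 for 4. Fry called 11, and 9 lists were called by both. By fry the interferon (adjusted p = 0.0671), absorptive colonocyte (0.0671), goblet cell (0.226), stem cell (0.334) and junction lists (0.411) were not called. Fry alone called the deacetylase inhibition (0.000266) and enteroendocrine lists (0.0363). In the first, 5 of 10 genes were higher and 3 lower, and in the second 4 of 14 were higher and 2 lower.

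The design also asks which changes of ampicillin tributyrin moved back. Slc16a1, Psmb8 and Fut2 were lowered by ampicillin and raised by tributyrin, Fut2 standing at 7.44 ± 0.970 TPM with mock gavage and rising by 0.85 ± 0.10 with tributyrin. Hk2, Insig1 and Mt1 were raised by ampicillin and lowered by tributyrin, Mt1 standing at 1640.1 ± 88.5 TPM after tributyrin. Of the genes changed by ampicillin, 595 were lowered and then raised and 411 were raised and then lowered, 1006 in all, or 47.8% and 30.6% of those lowered and raised by ampicillin. Independent lists would share 195 and 101, and 95 genes moved the same way in both comparisons. The 47.8% and 30.6% rest on how many genes tributyrin raised and lowered, a split that depended on the scaling. The total of opposite genes was 1134 with median-of-ratios scaling and 1137 with quantile normalization. Of the 1006, 702 were not called different from vehicle after tributyrin, 197 were still called on the ampicillin side and 107 were called on the far side of vehicle.

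Both comparisons use the same ampicillin libraries, so opposite signs arise with no effect at all. In 100 simulated data sets with no effect, 0.03 genes on average and at most 2 were called in both with opposite signs. Without an effect in either comparison a gene is seldom called at all. This number therefore cannot say how much of the overlap among the real calls came from the shared libraries. The covariance of the log2 fold changes across genes was -0.0670, against -0.0317 (SD 0.00328) in the simulations, a difference of -0.0353. The correlation was -0.459 against -0.501. Noise was simulated independently for each gene, while real genes can vary together, so the SD of the covariance may be too small. The 3 ampicillin libraries cannot be split into parts of at least 2, so part of the overlap may come from the shared libraries. Without ampicillin replicate 1, 2 or 3 the number of opposite genes was 617, 609 or 632. Against vehicle, 745 genes were higher and 562 lower in both ampicillin groups, 1307 in all, where independent lists would share 257 and 115, and 107 differed in opposite directions. Their covariance was 0.103, against 0.0312 in simulations that share the vehicle libraries, a difference of 0.0713, with the same limits.

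**Figure D4:**
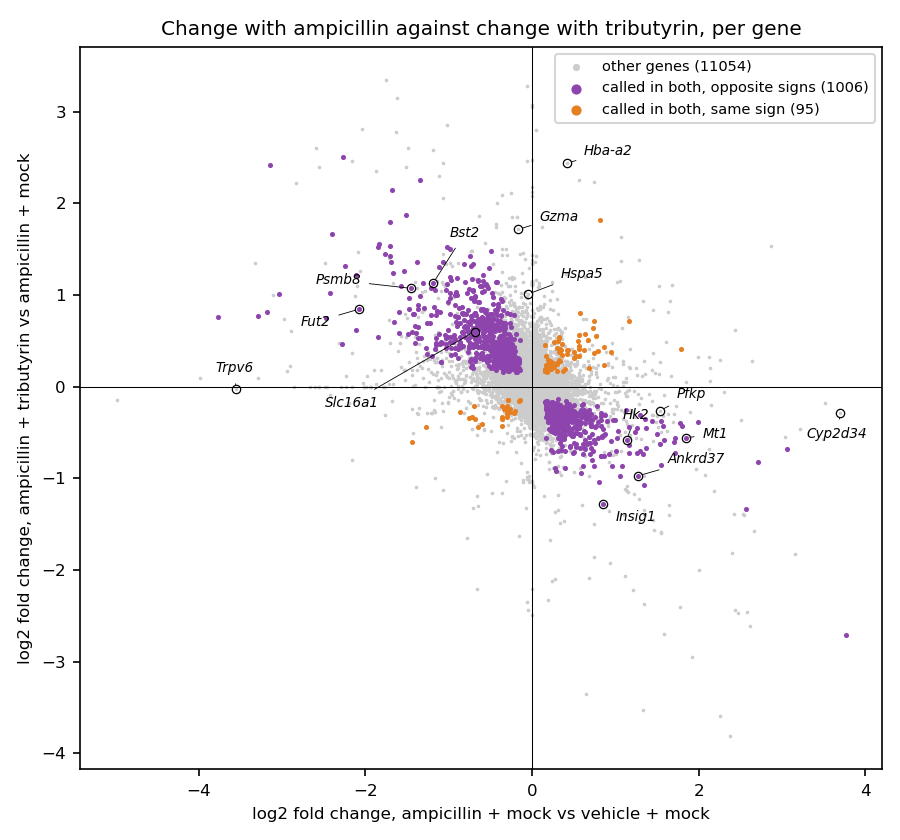
Log2 fold change of each of the 12155 genes with ampicillin (x axis) against its log2 fold change with tributyrin in ampicillin-treated mice (y axis), both on the log2(TPM + 1) scale. The 1006 genes called in both with opposite signs (purple) lie in the upper left and lower right, the 95 called in both with the same sign are orange, and ringed genes are named.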

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

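All alternatives except the removal of short RNA entries were planned; that 1 was chosen after the results were seen. For called lists, direction here is that of camera's test: 730 results kept it and their side of the threshold, and 81 kept it and lost the threshold, 37 of these with an estimated correlation. The median changed sign in 2 of the lost calls of ampicillin with tributyrin against vehicle, to 0.012 for stem cell markers without tributyrin replicate 3 and to 0.0083 for junction genes without vehicle replicate 2. For the butyrate and ketone list it was 0 with no filter. Of the results of named genes, 6979 kept both, 617 lost the threshold, 3 gained it and 4 reversed. All 4 were Ep300 with tributyrin against mock, never called, at -0.019 with median-of-ratios scaling, -0.038 with quantile normalization, -0.067 without tributyrin replicate 1 and -0.033 without tributyrin replicate 2. Its value without 1 library lay between -0.067 and 0.20. The cause was not tested.

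A minimum log2 change of 1 left 267, 116 and 199 genes in the 3 comparisons and 34 of the genes with opposite directions, by construction. Array weights, which count libraries by how well they match their group, raised the count for tributyrin against mock to 4271. An estimated correlation left 0, 0 and 0 lists called by camera, with unadjusted p under 0.05 for 2, 2 and 4 and smallest adjusted p of 0.0864, 0.311 and 0.303. Fry called 9, 11 and 11, of which 8, 9 and 9 were also called by camera at the preset correlation. A minimum mean TPM of 5 left 9 lists for ampicillin with tributyrin against vehicle. The cause of the last was not tested beyond the fewer genes it keeps.

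Leaving out 1 library at a time gave 1747 to 2785 genes for ampicillin against vehicle, 1574 to 2962 for tributyrin against mock, 2061 to 3766 for ampicillin with tributyrin against vehicle and 609 to 987 with opposite directions, and 10 to 13, 10 to 12 and 11 to 15 lists. Without vehicle replicate 2, in which small intestinal transcripts stood highest, the counts were 2254, 2766 and 2934, and 896 with opposite directions. Without short RNA entries they were 2696, 3060 and 3381, and 1132. The labels give the groups the same replicate numbers. Same-numbered libraries deviated together weakly at most (correlations between -0.0498 and 0.108, not above the threshold of 0.1 for each pair), so the numbers were not taken as pairs. In 10 of 18 cases a library matched its own number best, so some shared structure is not ruled out. With a replicate block the counts were 2707, 3009 and 3569, and 1107 with opposite directions, with 13, 12 and 15 lists. Depth is unknown, so what it limits for low genes could not be given; on simulated data, 59.7% to 74.6% of changes of 0.5 were recovered.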

Other observations

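The 8 tests of explanations below were chosen after their patterns had been seen, while the counts over other splits of the libraries were planned beforehand. Hormone genes of enteroendocrine cells moved in both directions with ampicillin: of 14 markers 3 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.670 by camera). Insl5, a peptide hormone of the large intestine, rose by 1.67 ± 0.17 and Cck, the gene of cholecystokinin, went from 3.10 ± 0.569 to 9.49 ± 1.95 TPM. Pyy, the gene of the satiety hormone peptide YY, changed by -1.57 ± 0.18. With tributyrin Pyy stood at 12.4 ± 3.55 TPM and 2 markers rose (adjusted p = 0.241), among them Tph1, the enzyme of serotonin synthesis, at 0.84 ± 0.14. Against vehicle 4 were higher and 2 lower, or 7 and 2 adjusted over the list alone (adjusted p = 0.186). Of 30 genes of xenobiotic metabolism, 11 rose and 13 fell with ampicillin (12 and 14 adjusted over the list alone, adjusted p = 0.535), 9 rose and 9 fell with tributyrin (10 and 11, 0.321), and 13 were higher and 10 lower after both (13 and 13, 0.274). Aldh1a1, an enzyme of retinoic acid synthesis, went from 323 ± 4.67 to 799 ± 63.5 TPM and the carboxylesterase Ces2a had a log2 fold change of -1.71 ± 0.11 after both treatments. Ion transport genes rose in 2 and fell in 2 of 24 cases with ampicillin (the same adjusted over the list alone, 0.316), rose in 4 and fell in 1 with tributyrin (the same, 0.623), and were higher in 6 and lower in 1 after both (6 and 2, 0.448). The chloride channel gene Cftr rose from 34.9 ± 3.63 to 54.8 ± 4.81 TPM with tributyrin. Among 19 junction genes 2 rose and 6 fell with ampicillin (2 and 7 adjusted over the list alone, 0.316), and 4 rose and 2 fell with tributyrin (4 and 3, 0.418), with Cldn2, which forms cation pores, going from 39.1 ± 5.76 to 24.6 ± 0.512 and then to 48.1 ± 7.08 TPM.

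Of 18 antimicrobial and microbiota-responsive genes, 6 rose and 7 fell with ampicillin (6 and 8 adjusted over the list alone, adjusted p = 0.551), 3 rose and 2 fell with tributyrin (3 and 3, 0.982), and 5 were higher and 5 lower after both (5 and 5, 0.274). Retnlb, a bactericidal goblet cell protein, stood at 383 ± 25.8, 120.0 ± 13.1 and 123 ± 23.3 TPM in vehicle, ampicillin and tributyrin libraries. The lists that follow were not called by camera, and counts are of higher and of lower genes. With ampicillin these were 2 and 5 of 19 PPAR-alpha targets (adjusted p = 0.0519), 1 and 3 of 15 lipid absorption genes (0.162), 0 and 5 of 13 fatty acid synthesis genes (0.0734). They were 2 and 0 of 5 MHC class II genes (0.162), 2 and 0 of 16 clock genes (0.211), 6 and 2 of 22 unfolded protein response genes (0.763). They were also 2 and 0 of 34 lysine acylation genes (0.972), 4 and 3 of 10 genes raised by deacetylase inhibition (0.664). For cell markers they were 2 and 3 of 9 small intestinal enterocyte markers (0.551), 0 and 2 of 7 myeloid markers (0.560). Of 6 bile acid genes 3 were higher and 1 lower (0.227, with a median of 0.25 and a mean of -0.35). By limma 0 of 14 T cell and 0 of 7 tuft cell markers were called, with 0 and 1 at an unadjusted p under 0.05 (0.683 and 0.872 by camera). With tributyrin they were 4 and 0 of 19 beta-oxidation genes (0.208), 4 and 0 of 15 lipid absorption genes (0.637), 2 and 1 of 13 fatty acid synthesis genes (0.418). Among cell markers they were 2 and 0 of 15 stem cell (0.973), 1 and 0 of 15 goblet cell (0.996), 1 and 0 of 7 tuft cell (0.790), 4 and 3 of 17 absorptive colonocyte (0.798) and 2 and 0 of 9 small intestinal markers (0.721). By limma, 0 were called for Paneth cell (0.930), MHC class II (0.241) and myeloid genes (0.791), with 0, 3 and 0 at an unadjusted p under 0.05. After both treatments against vehicle they were 2 and 6 of 19 beta-oxidation genes (0.241), 7 and 3 of 19 PPAR-alpha targets (0.321), 4 and 2 of 15 lipid absorption genes (0.390). Next were 3 and 2 of 45 oxidative phosphorylation genes (0.390), 3 and 1 of 33 cell cycle genes (0.274), 1 and 2 of 9 small intestinal markers (0.274). There were 1 and 1 of 6 bile acid genes (0.335), 2 and 5 of 16 clock genes (0.0572), 6 and 1 of 34 lysine acylation genes (0.910). The rest were 5 and 3 of 10 genes raised by deacetylase inhibition (0.448), 0 and 2 of 7 myeloid (0.335) and 0 and 0 of 7 tuft cell markers (0.448), 1 of them at an unadjusted p under 0.05 in limma.

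Median, mean and test had the same sign in each called list. Among lists not called they differed with ampicillin for bile acid, lysine acylation, deacetylase inhibition, myeloid, small intestinal and unfolded protein genes, and with tributyrin for Paneth cell, antimicrobial, junction, fatty acid synthesis, lysine acylation, myeloid, small intestinal and xenobiotic genes. Against vehicle after both treatments they differed for ion transport, myeloid, oxidative phosphorylation and xenobiotic genes. Lists with fewer than 4 measured genes were not tested as lists. Of 3 endothelial genes, 2 fell with ampicillin, 3 rose with tributyrin and 1 was higher and 1 lower after both. Of 2 erythroid genes, 2 rose with tributyrin, of 3 mast cell genes 1 was higher after both, and of 2 smooth muscle genes 1 was lower in both ampicillin groups. The single measured B cell, fibroblast and pancreatic acinar genes were not called by limma in any comparison, with 0 at an unadjusted p under 0.05, and none of the mitochondrially encoded genes was among those used here. Of the sex-linked genes, Xist, which female cells express, stood at 19.2 to 33.8 TPM in the 9 libraries and Y-linked genes at no more than 0.299 TPM.

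A first pattern was the loss of small intestinal and Paneth cell transcripts with ampicillin. All 17 markers that averaged under 1 TPM with ampicillin were highest in vehicle replicate 2. Their median log2 ratio of TPM + 0.1 to replicate 1 was 3.71 (quartiles 2.66 and 4.19). Markers had to reach 1 TPM in a vehicle library. Some, such as Sis and Abcg5, did so only in replicate 2, which fixed their rank, while others, such as Defa24 and Apoa1, also did so in replicate 3. The ratio is enlarged because its 2 libraries were chosen from these same values as highest and lowest. Small intestinal RNA in replicate 2 would give such a pattern, so a small intestinal source may account for much of the loss. A response of the caecum cannot be told apart from it for these markers, since 1 of the 3 that could be tested without that library, Apoa1 (log2 fold change -2.06), was still called, against 5 of 8 with all libraries. Outside the 17, 9 genes of the small intestinal, Paneth cell, bile acid and lipid absorption lists were called lower with all libraries and 7 of them stayed so without it, Fabp6 (-2.76) and Anpep (-1.05) among them. Reg3b (-3.78) and Reg3g (-1.91), of the antimicrobial list, stayed called lower too. These 4 were singled out after their values were seen. Vehicle replicate 3 also stood above replicate 1, with Defa30 at 5.81 against 0.931 TPM and Apoa1 at 9.19 against 2.30 TPM. Leaving out replicate 2 therefore need not remove all small intestinal RNA, and genes that stayed called may still owe their fall to it. For the goblet cell list, small intestinal RNA in replicate 2 would have to raise that library over replicate 1 by at least the median fall with ampicillin, 0.295. Over all 15 goblet cell markers the median log2 ratio of TPM + 0.1 between the same libraries was -0.0814 (quartiles -0.193 and 0.0528), and the 5 that were called lower, Muc2, Klk1, Creb3l1, Galnt12 and Spink4, all stayed called without vehicle replicate 2. This argues against small intestinal RNA as the cause of the lower goblet cell genes and leaves a response to ampicillin open as a hypothesis. The fall of the list itself rests in part on vehicle replicate 1, without which camera did not call it (adjusted p = 0.285). For the 9 Paneth and deep crypt secretory markers the ratio had a median of 3.71 (quartiles 1.77 and 4.70) against a median fall of 1.90, so small intestinal RNA and a response cannot be told apart for this list, whose members differ: of the 7 called lower, Mptx1 and Reg4 stayed called without replicate 2, Ang4 did not, and the 3 defensins and Itln1 no longer passed the filter.

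A second pattern was higher haemoglobin and T cell transcripts after tributyrin. A lower share of epithelial cells would raise all other cells alike, but as log2 ratios of mean TPM + 0.1 to mock, the lowest haemoglobin value exceeded the upper quartile of 14 T cell genes by 1.37 (2.29 against 0.921), which argues against it as the one cause of both. On the log2(TPM + 1) scale, 3 of 3 endothelial genes rose (median 0.70), near the T cell median of 0.67. The 3 mast cell genes, not called, had a median of 0.58 but a lower quartile of 0.19. Other lists rose less, with a median of 0.0021 for 7 myeloid genes and -0.096 for 2 smooth muscle genes. The myeloid genes did not vary together (estimated correlation -0.012, against 0.733 for T cell genes), so they may not track 1 cell type. Their top gene Ctss averaged 231 TPM over the libraries, against 23.6 TPM for the top T cell gene Ccl5. These flat values therefore cannot show that non-epithelial cells failed to rise. The single fibroblast and B cell genes changed by 0.12 and 0.25. With so few genes and mixed values, a lower epithelial share stays open for the T cell part. Blood as the one source of both cannot be told apart from separate sources: from tributyrin replicate 1 to 2 the haemoglobin genes were lower (log2 ratios of TPM + 0.1 of -0.157 and -0.378) and the T cell genes higher (median 0.628), but the gap of 0.606 to the lower quartile of the T cell genes is below the 0.788 by which these genes typically ranged among the mock libraries. More intraepithelial lymphocytes may also explain the T cell part, and a change in the tissue and a difference in how cells were isolated stay open, since the labels name no sort that would remove these cells.

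A further pattern was the rise of immediate early genes in both ampicillin groups and of heat shock genes after tributyrin. A single stress raising both in proportion is argued against: with ampicillin, 16 immediate early genes had a median of 0.49 while 4 heat shock genes had one of -0.15, a gap of 0.231 between the lower quartile of the first and the highest of the second, and with tributyrin the medians were 0.27 and 1.54. Handling that differed between groups could raise immediate early genes, and within groups these genes did deviate together, with a median correlation of 0.554 against at most 0.358 in 100 random sets. That pattern within groups does not show what separates the groups, so handling and a response to treatment cannot be told apart here for the immediate early genes, and no test bore on whether butyrate itself raised the heat shock genes.

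Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05. The real splits called 2587, 2819 and 3444 genes, against at most 5, 4 and 3 in the others, and the real split was the only 1 with as many genes in each comparison. For lists the real splits called 12, 11 and 14, against at most 12, 10 and 12 in the others. With ampicillin 2 of 10 splits gave as many. Camera at the preset correlation thus called nearly as many lists in some mixed splits, so its list p-values may be too small. For opposite directions, 2 of 100 assignments of the 9 libraries gave at least the real 1006 genes, a share under 0.05. The other of these 2, with 1307, kept the groups whole under other names. Among the 98 assignments that mixed the groups, the highest gave 637. Mixing libraries of groups that differ in any way lowers such counts of opposite genes, so the share bears only on whether the groups differ. It cannot show that tributyrin moved the changes of ampicillin back.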
